A study of Mus musculus with 9 samples.

How the data were processed

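Gene expression was measured in mouse embryonic stem cells on 9 Affymetrix arrays, 3 for each of 3 groups. Per the labels' protocols, cells were grown without feeder cells on gelatin in serum with LIF, total RNA was purified on spin columns, and biotin-labelled cRNA was made with the Affymetrix 3′ IVT Express kit. Per the labels' protocols, recombination was induced with 500 nM 4-hydroxytamoxifen; the time between treatment and harvest is not given in the sources used here.

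The authors deposited 1 table of log2 expression values, with 45101 probe sets in rows and the 9 arrays in columns. Per the submitters' processing notes the arrays were analysed with limma, and the background correction, the normalization between arrays and the way probes were summarised into probe sets are not given in the sources used here. The deposited log2 values ran from 2.56 to 15.04, and the medians of the 9 arrays lay between 5.61 and 5.67. After sorting, values of the same rank lay within 0.09 log2 units of their mean over the arrays, so the arrays had nearly the same distribution as deposited. A change in the total RNA content of the cells would be removed by values of this kind. The pseudocount planned for linear values was not used because the values were already on the log2 scale.

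Probe sets were paired with genes through the platform annotation, with symbols brought up to date by Entrez identifier from the RefSeq annotation of GRCm38.p6. Of the probe sets, 64 were array controls and were left out, 34945 had 1 gene symbol, 932 had several and 9160 had none. The Entrez identifiers of 204 probe sets with 1 symbol were not in the RefSeq table and kept their old symbol. Probe sets with several symbols or none were not named or tested as genes. For each gene the probe set with the highest mean over all 9 arrays was used, which gave 18193 genes, of which 9010 had more than 1 probe set. The sources used here name no genome build, so no coordinates are given.

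The computations used R 4.3.3 and limma 3.58.1. All 9 arrays entered a single linear model of 3 group means (lmFit, eBayes with the default prior), with 6 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Standard errors (SE) are the moderated ones of that model, and group values are means with the SD over 3 arrays. Comparisons were Cre plus tamoxifen against Cre minus tamoxifen, Cre plus tamoxifen against no Cre plus tamoxifen, and Cre minus tamoxifen against no Cre plus tamoxifen. Genes that passed with the same sign in both comparisons of the Cre plus tamoxifen group were counted, as was the contrast of that group with the mean of both controls. The labels number the arrays 1 to 3 within each group and do not say whether they are separate cultures, so the p-values measure only the spread between these arrays, which may be technical. With arrays, the number of samples and not a read depth limits the precision.

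The comparisons, the tests, the gene lists, the rule for the genes to be named and the alternatives were fixed before the data were examined. The 15 lists were H3K9 methylation and silencing machinery, trophectoderm and trophoblast, pluripotency, primitive endoderm, primitive streak and mesoderm, neuroectoderm, 2-cell stage, germline, imprinted genes, p53 targets, interferon response, proliferation, stress response, cholesterol synthesis and, for another cell type, fibroblasts. Together they held 367 entries, of which 324 were measured, 1 of them through a synonym (Tex13b, written as Tex13). Ascl2 was in 2 lists. Each list was tested with limma's camera with a preset correlation of 0.01 between genes and adjustment over the 15 lists within a comparison, and again with an estimated correlation. The rule for named genes took Setdb1, Pou5f1, Nanog, Sox2, Cdx2, Eomes, Gata3, Tfap2a, Hand1, Tpbpa and Dazl whatever their values. It added the 10 genes that rose most and the 10 that fell most against both controls, by the smaller of the 2 differences. It also took up to 4 members of each list with the lowest adjusted p in Cre plus against Cre minus tamoxifen, and the 5 most raised and 5 most lowered genes between the controls. List members that make up a count of 5 or fewer, and the genes of the additional observations, were named after their values were seen.

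The alternatives were quantile normalization or median centring on top of the deposited values, a filter at the 40th percentile of mean expression, every probe set on its own, the mean of a gene's probe sets, and probe sets of the x and s types left out. Further ones were a trended and robust prior, fits of only the groups compared, the replicate number as a block, a 2-fold minimum, each array left out in turn, an estimated correlation and the fry test for lists. A fit without the third arrays of both Cre groups was added after the data were seen.

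The procedure was tested on simulated data of 18193 genes with the spread of the real arrays. Of 50 genes per size changed by 0.25, 0.5, 1 and 2 log2 units in Cre plus against Cre minus tamoxifen, 24%, 72%, 98% and 100% were recovered, with 11 false calls among the other genes. Against no Cre plus tamoxifen the shares were 22%, 66%, 96% and 100%, with 10 false calls. Far fewer genes changed in the simulation than the 56.1% and 59.3% called in the real comparisons. The Benjamini-Hochberg cutoff depends on that share, so neither the recovery nor the number of false calls carries over to the real data. With no simulated change between the controls limma called 0 genes, and 931 had an unadjusted p under 0.05. In Cre plus against Cre minus tamoxifen, a list shifted by 0.5 log2 units was called.

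Pairs of arrays within a group correlated at 0.9966 to 0.9981 over all probe sets. The SD of their differences was 0.109 to 0.139 over genes above the 40th percentile of mean expression, so no array was a copy of another. Some genes did hold identical values. Among the genes plotted array by array in the results, this occurred only in Cre without tamoxifen. There Cdx2 (7.24), Gata3 (6.41) and Krt7 (9.09) were identical on arrays 1 and 2. Sox2 (12.78) and Usp17la (10.70) were identical on arrays 2 and 3. Phlda3, Mphosph8, Ddit4l and Hand2 had an SD of 0 over the 3 arrays of that group. Amn had an SD of 0 without Cre, and Usp26 with Cre and tamoxifen. Such ties lower the SD and SE of these genes, and their cause was not tested. Above that percentile, the median SD of Cre without tamoxifen (0.0608) was not below those of the other groups (0.0549 and 0.0562). Spiked-in transcripts differed between groups. Of their 45 probe sets, 3 were called in Cre plus against minus tamoxifen, 17 in Cre plus against no Cre and 9 between the controls, all lower, by at most 0.49, 0.76 and 0.46 (medians over the 45 of -0.053, -0.18 and -0.14). Whether the RNA input, the labelling or the scaling caused this was not tested. Spiked-in bacterial transcripts also showed 1 array apart from the rest in the decline towards the 5′ end. On the third Cre plus tamoxifen array the dap transcript was 3.54 log2 units higher at its 3′ than at its 5′ probe set, against at most 1.55 on the other 8, and the thr transcript 3.28 against at most 1.64. The lys and phe transcripts showed no such decline there (1.21 and 1.18, within 0.94 to 1.34 and 1.08 to 1.52 on the other 8). The 18S rRNA 5′ signal was 12.0 on that array and 12.1 on the third Cre minus tamoxifen array, against 12.5 to 13.6 on the others. The same difference for the cells' own transcripts stayed between -0.12 and -0.027 for Gapdh and between 0.119 and 0.31 for β-actin on all 9 arrays. For the transferrin receptor it was 1.02 on the third Cre minus tamoxifen array, against -0.76 to 0.34 on the other 8. The control probe sets for Cre detect a spiked-in hybridization control and do not measure the transgene.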

Results

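The study asked what the loss of SETDB1 (also called KMT1E), an enzyme that methylates lysine 9 of histone H3, does to gene expression in mouse embryonic stem cells. The cells carried a conditional Setdb1 allele (genotype 2lox/1lox), from which the Cre recombinase can remove a part flanked by loxP sites. Tamoxifen switches on the inducible form of Cre. Expression was measured on 9 arrays in 3 groups of 3. Cells with Cre and tamoxifen are the group in which Setdb1 was to be deleted. Cells with Cre but no tamoxifen and cells without Cre but with tamoxifen are its controls. The spread was taken over genes above the 40th percentile of mean expression. Their median SD over the 3 arrays of a group was 0.0549 log2 units without Cre. It was 0.0608 with Cre and no tamoxifen, and 0.0562 with Cre and tamoxifen.

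Setdb1 itself was lower in the group meant to lack it. Its log2 value was 7.33 ± 0.015 (SD, n = 3) with Cre and tamoxifen, 8.96 ± 0.061 with Cre alone and 8.61 ± 0.034 with tamoxifen alone. It fell by 1.63 (SE 0.047, adjusted p = 2.12e-09) against Cre alone, a 3.09-fold decrease, and by 1.28 (SE 0.047, adjusted p = 7.72e-09) against tamoxifen alone. Setdb1 was 0.35 higher (SE 0.047) with Cre alone than with tamoxifen alone. Of the other Setdb1 probe sets, both were dim, with a mean log2 value of 4.75 and 4.72 over the arrays. Whether the probes lie in the part removed by Cre is not given in the sources used here, so the residual signal does not measure the share of deleted cells.

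The first comparison set Cre plus tamoxifen against the same cells without tamoxifen, which asks what changes when the deletion is induced. Transcription factors of the pluripotent state fell. Pou5f1, which encodes OCT4, fell by 2.03 (SE 0.052), Nanog by 2.34 (SE 0.078) and Sox2 by 2.30 (SE 0.040), each to between 4.08-fold and 5.07-fold less. Genes of the trophectoderm, the outer lineage of the blastocyst that forms the placenta, rose: Cdx2 by 1.08 (SE 0.136), Gata3 by 1.90 (SE 0.082), Hand1 by 1.60 (SE 0.155) and Tfap2a by 0.56 (SE 0.146). Dazl, an RNA-binding protein of germ cells, rose by 1.85 (SE 0.050). Eomes, a T-box factor of trophoblast stem cells, differed by 0.04 (SE 0.104, limma adjusted p = 0.769). Tpbpa, a marker of the later spongiotrophoblast, differed by -0.048 (SE 0.070, limma adjusted p = 0.595). Its group means of 3.99 to 4.03 lay below the 25th percentile of the arrays (4.13 to 4.21), so it may not be expressed in any group.

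**Figure D1:**
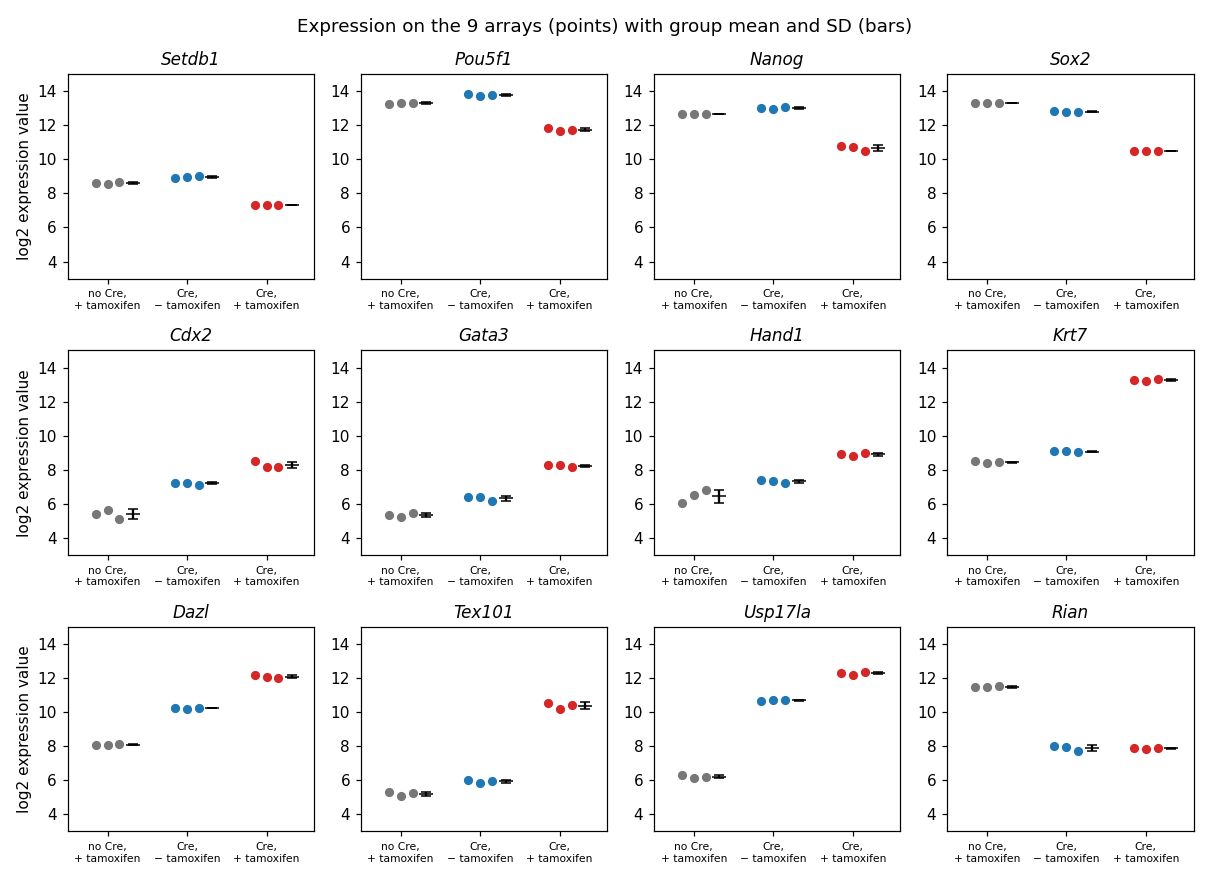
Log2 expression values (vertical axis) of 12 genes on the 9 arrays, grouped on the horizontal axis as no Cre with tamoxifen, Cre without tamoxifen and Cre with tamoxifen, 3 arrays each. Points are arrays, and the bar beside each group is its mean with the SD; Krt7 went from 9.07 to 13.27 in the Cre cells with tamoxifen, while Rian was at 7.88 and 7.87 in the Cre groups and 11.48 without Cre.

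Of 28 measured trophectoderm and trophoblast genes, 25 rose, the same number as adjusted over the list alone, and Eomes, Elf5 and Tpbpa were not called. Krt7, a keratin of simple epithelia, rose by 4.20 (SE 0.049, 18.4-fold). The X-linked homeobox genes Rhox6 and Rhox9 rose by 4.47 and 4.71, and the galectin Lgals3 by 3.78. The list had a median difference of 1.43 and was called (camera adjusted p = 1.44e-12). Of 26 pluripotency genes, 24 fell, again 24 when adjusted over the list alone. The growth factor gene Fgf4 fell by 4.12 (SE 0.042), the nuclear receptor gene Esrrb by 2.65, and Klf4 by 2.95. Dppa3, which is also expressed in germ cells and preimplantation embryos, rose by 1.01, and Stat3 was not called. The median of the list was -1.64 (adjusted p = 3.18e-12).

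Germline genes rose as a group. Of 27 measured, 21 rose and Dmc1 and Syce1 fell, with the same counts adjusted over the list alone, and the median was 0.85 (adjusted p = 6.82e-07). Tex101, which encodes a germ cell surface protein, rose by 4.44 (SE 0.100), and Sycp3, part of the synaptonemal complex of meiosis, by 2.13. Mael, which acts in the piRNA pathway, rose by 1.40. Of 27 listed genes expressed at the 2-cell stage of the embryo, only 11 were measured. Of these, 8 rose, Pramel6 and Pramel7 fell, and Lgals4 was not called, as when adjusted over the list alone. Usp17la rose by 1.59 (SE 0.056), Zfp352 by 1.39 and Sp110 by 1.74, while Pramel6 fell by 2.43. The probe sets of Sp110 disagreed. That of the x type, with a mean log2 value of 6.24 over the arrays, differed by 0.14 and was not called. The remaining probe set was dim (3.85) and rose by 0.22. The median of the list was 0.97 (camera adjusted p = 0.00615). Pramel6 was read by a probe set of the s type, which can detect related transcripts, and its other probe set fell by 0.52. It ended at 3.41, below the 25th percentile of the arrays (4.13 to 4.21), so its fall of 2.43 is a lower bound. Imprinted genes, which are expressed from the allele of a single parent, had 18 of 35 higher and 7 lower (18 and 7 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.00696). Among them the growth factor gene Igf2 rose by 2.88, Ndn by 1.51, the noncoding Airn by 2.17 and Sgce by 2.11. With genes below the 40th percentile of expression left out, the imprinted list was not called (adjusted p = 0.0503).

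Genes of the H3K9 methylation and silencing machinery were mostly lower. Of 27, 20 fell, as did 20 adjusted over the list alone. Atf7ip, Pphln1 and Zfp809 rose, with 1 more riser adjusted over the list alone, and the median was -0.33 (adjusted p = 0.000247). Beside Setdb1, Trim28, the corepressor that recruits SETDB1, fell by 1.36 (SE 0.044), and Cbx1, which encodes the heterochromatin protein HP1β, by 1.36. The probe sets of the DNA methyltransferase gene Dnmt3a disagreed: the brightest fell by 2.11 (SE 0.049), 2 others fell by 2.46 and 0.56, and 2 rose by 0.66 and 1.17. Of 18 proliferation genes, 16 fell, also 16 adjusted over the list alone, and Mki67 and Cdk1 were not called. The replication helicase genes Mcm5, Mcm6, Mcm2 and Mcm7 fell by 1.00, 0.88, 0.90 and 0.83, and the median was -0.60 (adjusted p = 4.87e-06). Of 21 targets of the tumour suppressor p53, 16 rose and Sesn1 and Sesn2 fell (17 and 2 adjusted over the list alone), with a median of 0.39 (adjusted p = 0.000247). The cell cycle inhibitor gene Cdkn1a rose by 1.41 (SE 0.052), and Perp, Phlda3 and Ccng1 by 1.76, 0.92 and 0.73.

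Of 19 genes typical of fibroblasts, 13 rose and Thy1 and Fbln1 fell, with the same counts adjusted over the list alone and a median of 0.55 (adjusted p = 0.00135). The smooth muscle protein gene Tagln rose by 3.31, Pdgfrb by 1.37 and Col5a2 by 1.13, while Col1a1, the main fibrillar collagen of fibroblasts, differed by 0.24 and was not called. Acta2 was 3.65 higher on a probe set of the s type, which can detect related transcripts. Its other probe sets differed by 0.016 and -0.019 without being called. Those were dim, with a mean log2 value of 3.59 and 3.71 over the arrays, so they do not weigh against the rise. The fibroblast list was not called with the filter on dim genes (adjusted p = 0.0808). The remaining lists were not called. Of 20 primitive endoderm genes, 9 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.0512). This list lay at the threshold and was called higher under 12 of 20 alternatives, but not with an estimated correlation (adjusted p = 0.0903). It had higher values for the basement membrane collagen genes Col4a1 (2.66) and Col4a2 (3.10) and for Sparc (1.25) and lower ones for the laminin gene Lama1 (-2.03), Sox7, Hnf4a and Amn. Of 20 primitive streak and mesoderm genes, Wnt3, Snai1 and Lefty2 (1.04) rose and 7 fell (adjusted p = 0.403), including Nodal (-1.73), Lefty1 (-1.25) and Bmp4 (-0.53). Of 19 neuroectoderm genes, Pax3, Zic1, Zic2 and Nes (0.93) rose and 8 fell (adjusted p = 0.197), including Gbx2 (-3.76), Neurod1 (-2.63) and Sox3 (-1.27). Of 21 interferon response genes, 6 rose, including Cxcl10 (2.87), Rsad2 (1.35) and Bst2 (0.94), and Ifit2, Oas1a, Zbp1 and Ddx58 (-1.57) fell (adjusted p = 0.504). Of 16 cholesterol synthesis genes, Stard4 (0.67), Sqle (0.68), Hmgcs1, Sc5d and Srebf2 rose and 9 fell, including Ebp (-0.79) and Insig1 (-0.50), with adjusted p = 0.504. The rises and falls in these 4 lists were as many when adjusted over the list alone. Of 16 stress response genes, 10 rose and 5 fell (10 and 6 adjusted over the list alone; adjusted p = 0.101). The risers included the immediate early gene Fos (1.75), Gadd45b (1.78) and Ier3 (1.68), and the genes that fell were Egr1 (-1.74), Ier2, Gadd45a, Chac1 and Asns.

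Over all 18193 genes, limma called 10198 (56.1%) in this comparison, 4957 higher and 5241 lower. With arrays centred on their medians the balance turned, to 5343 higher and 4683 lower, so it depends on the scaling. Of the 10198, 2057 differed at least 2-fold, 1387 higher and 670 lower. All 9 called lists stayed called with an estimated correlation, the highest value being an adjusted p = 0.0359 with an estimated correlation. The comparison joins the deletion with the drug and with active Cre, since only 1 of the groups received tamoxifen. The third Cre plus tamoxifen array stood apart in the spiked-in transcripts; without it and the third Cre minus tamoxifen array the number called was 9523.

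**Figure D2:**
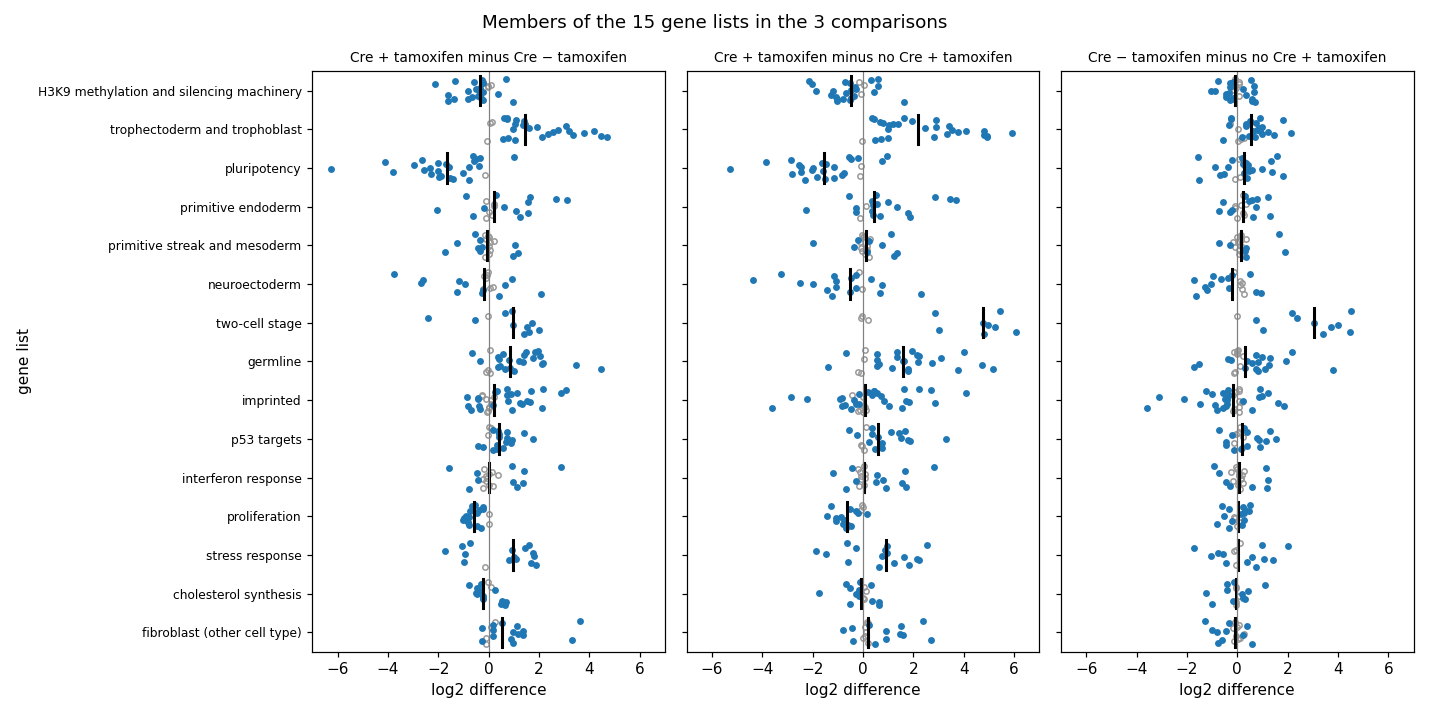
Log2 differences (horizontal axes) of the measured members of the 15 gene lists (vertical axis) in the 3 comparisons. Each point is a gene, filled where it was called and open where it was not, and the black line is the list's median: 1.43, 2.20 and 0.53 for trophectoderm and 0.97, 4.78 and 3.04 for the 2-cell stage, from left to right.

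The second comparison set Cre plus tamoxifen against cells without Cre that also received tamoxifen, so that the drug was the same in both. Pou5f1 fell by 1.57 (SE 0.052), Nanog fell by 1.98 (SE 0.078) and Sox2 fell by 2.82 (SE 0.040). Cdx2 rose by 2.90 (SE 0.136), Gata3 by 2.90 (SE 0.082), Hand1 by 2.46 (SE 0.155), Tfap2a by 0.71 (SE 0.146) and Eomes by 0.78 (SE 0.104). Dazl rose by 4.01 (SE 0.050), which is 16.1-fold, and Tpbpa differed by -0.032 (adjusted p = 0.726). Of the 28 trophectoderm and trophoblast genes, 27 rose, also 27 adjusted over the list alone. The exception was Tpbpa, whose signal was near background in all groups. Lgals3 rose by 5.93 (SE 0.055) and Krt7 by 4.83, and the median of the list was 2.20 (adjusted p = 1.27e-12). Of the 26 pluripotency genes, 22 fell and Dppa2 and Fbxo15 rose, with the same counts adjusted over the list alone and a median of -1.53 (adjusted p = 6.92e-10). Fgf4 fell by 3.85, Esrrb by 2.87 and Klf4 by 2.54.

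Of the 11 genes of the 2-cell stage, 8 rose, also 8 adjusted over the list alone, with a median of 4.78 (adjusted p = 1.01e-05). Usp17la rose by 6.07 (SE 0.056), Zfp352 by 4.80 and Sp110 by 4.78, while Pramel6 differed by -0.070 (limma adjusted p = 0.488). The other Sp110 probe sets differed by 0.13 (x type, not called) and 0.29 (dim). Both Pramel6 values (3.41 and 3.48) lay below the 25th percentile of the arrays (4.13 to 4.21), so its difference compares signals near background. Of 27 germline genes, 21 rose and Dmc1 and Tdrd12 fell, as when adjusted over the list alone, with a median of 1.58 (adjusted p = 1.03e-06) and rises of 5.18 for Tex101 and 2.16 for Mael. Of the 27 silencing genes, 19 fell and 5 rose, namely Atf7ip, Atf7ip2, Dnmt3l, Morc2a and Zfp809, with the same counts adjusted over the list alone and a median of -0.47 (adjusted p = 0.000246). Trim28 fell by 0.78 and Cbx1 by 2.13. Of the 18 proliferation genes, 14 fell and Cdk1 rose, as when adjusted over the list alone, with a median of -0.63 (adjusted p = 1.98e-05). Of the 21 p53 targets, 15 rose and Bbc3 and Ei24 fell, as when adjusted over the list alone, with a median of 0.60 (adjusted p = 0.000408) and rises of 3.31 for Perp and 1.44 for Cdkn1a. Of the 19 neuroectoderm genes, 13 fell and 4 rose, namely Pax3, Nes, Zic1 and Tubb3, with the same counts adjusted over the list alone and a median of -0.51 (adjusted p = 0.00562). The proneural factor gene Neurod1 fell by 4.36 (SE 0.062).

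Primitive endoderm genes were called higher (14 rose and Hnf4a, Amn, Lama1 and Lamc1 fell of 20, 14 and 5 adjusted over the list alone; median 0.46; adjusted p = 0.0235), but not with an estimated correlation (adjusted p = 0.061) or the filter on dim genes (adjusted p = 0.274). Fibroblast genes were called higher (9 rose and Thy1, Fn1 and Fbln1 fell of 19, as when adjusted over the list alone; median 0.22; adjusted p = 0.0259). That call was lost with an estimated correlation (adjusted p = 0.0621), with the filter on dim genes (adjusted p = 0.35) and without probe sets of the x and s types (adjusted p = 0.069). Stress response genes were called higher (11 rose and Egr1, Ddit3, Ier2, Gadd45a and Asns fell of 16, as when adjusted over the list alone; median 0.92; adjusted p = 0.0491). This call lay at the threshold and was lost under 9 of 20 alternatives, among them an estimated correlation (adjusted p = 0.0894). The 35 imprinted genes had 16 higher and 12 lower (16 and 13 adjusted over the list alone; adjusted p = 0.398). In this list Igf2 rose by 4.09, while the noncoding RNA gene Rian fell by 3.60. The interferon, cholesterol and primitive streak lists were not called (adjusted p = 0.398, 0.398 and 0.429).

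Limma called 10781 genes (59.3%), 5601 higher and 5180 lower, and 2439 of them differed at least 2-fold, 1503 higher and 936 lower. Of 45 probe sets for spiked-in transcripts, 17 were called too, all of them lower and by 0.15 to 0.76, so a small called difference need not come from the cells. The 8 called lists other than the 3 above stayed called with an estimated correlation, the highest value being an adjusted p = 0.0476 with an estimated correlation. The comparison joins the deletion with active Cre and with any difference between the cells with and without Cre.

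Genes that changed in the same direction against both controls included some of the largest differences on the arrays. Among genes read by probe sets with 1 symbol, the 10 that rose most were led by 1600025M17Rik, a gene known by its clone name (5.30 against Cre alone and 5.43 against tamoxifen alone), and by Igfbp6, a binding protein of insulin-like growth factors (4.85 and 4.97, SE 0.126 each). Next came the orphan receptor gene Gpr50 (4.82 and 5.75), Rhox9 (4.71 and 4.91), the pantetheinase gene Vnn1 (4.48 and 5.72), Rhox6 (4.47 and 4.93), Tex101 (4.44 and 5.18), Ankrd1 (4.39 and 4.35), D7Ertd128e (4.33 and 4.81) and Krt7 (4.20 and 4.83). In the controls 1600025M17Rik (3.76 and 3.90) and D7Ertd128e (3.69 and 4.16) lay near or below the 25th percentile of the arrays (4.13 to 4.21), so their differences are lower bounds and their ranks approximate. Gpr50 did so with tamoxifen alone (3.53), so its 5.75 is a lower bound too. Of the probe sets with no symbol or several, the 2 that rose most by the smaller difference exceeded the 10 genes above and were not named. Their differences were 6.35 and 7.41 for the first and 5.77 and 5.73 for the second. How many others exceeded these genes was not counted. The gene that fell most was Nr0b1, an orphan nuclear receptor of the pluripotency network (-6.27 and -5.28, SE 0.136 each), from a log2 value of 11.15 ± 0.026 (SD, n = 3) with Cre alone and 10.16 ± 0.022 with tamoxifen alone to 4.88 ± 0.345. It was followed by the Rho exchange factor gene Mcf2 (-4.19 and -4.36), Fgf4 (-4.12 and -3.85), Apela, which encodes a ligand of the apelin receptor (-3.72 and -5.47), the actin regulator gene Cobl (-4.05 and -3.72) and the myoblast fusion gene Mymx (-3.60 and -4.22). The last of the 10 were the Hedgehog effector gene Gli2 (-3.49 and -3.81), Tcl1 (-3.48 and -3.31), the glutathione peroxidase gene Gpx2 (-3.29 and -3.96) and the homeobox gene Gbx2 (-3.76 and -3.27).

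In all, 7242 genes (39.8%) were called with the same sign against both controls, 3824 higher and 3418 lower (3640 and 3661 with quantile normalization, so the balance depends on the scaling), and 1019 were called with opposite signs. At least 2-fold in both were 1357, of which 974 were higher and 383 lower. Independent lists of these sizes would share 1526 higher and 1492 lower genes. In 100 simulations of unchanged groups that share the Cre plus tamoxifen arrays, limma called 0 genes in both, with a median of 215.5 at an unadjusted p under 0.05 in both. The differences of the 2 comparisons correlated at 0.778 across genes, which are not independent replicates, against 0.5 in the simulations, and their covariance was 0.412 against 0.00337. With 3 shared arrays no split with 2 in each part was possible, so part of the excess may come from the shared arrays. Active Cre is also common to both comparisons, and no group had it without the deletion. Its effect therefore cannot be told apart from that of the deletion. Against the mean of both controls limma called 10728 genes, 5356 higher and 5372 lower (5621 and 4977 with arrays centred on their medians).

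The third comparison set the controls against each other, Cre without tamoxifen against no Cre with tamoxifen. It gives the background of the other comparisons and joins the drug with any difference between the cells. Genes of the 2-cell stage had the largest median difference of the 15 lists. Only 11 of the 27 listed genes were measured. Of these, 10 rose in the cells with Cre, also 10 adjusted over the list alone, and Lgals4 was not called. Usp17la rose by 4.49 (SE 0.056), AF067061 by 4.52 (SE 0.058), Zfp352 by 3.42, Sp110 by 3.04 and Pramel6 by 2.36. The median of the list was 3.04 (camera adjusted p = 3.6e-08). The other Sp110 probe sets differed by -0.018 (x type) and 0.074 (dim), and neither was called. AF067061 was read by a probe set of the x type and Pramel6 by a probe set of the s type. Without Cre, Pramel6 lay at 3.48, below the 25th percentile of the arrays (4.13 to 4.21), so its 2.36 is a lower bound. The list stayed called, with adjusted p = 0.0115 with an estimated correlation. Other genes that were most raised were Gm20767 (5.54), BC080696 (4.87) and the arginase gene Arg2 (4.85), each higher still with Cre and tamoxifen. Without Cre they lay at 4.33, 4.32 and 4.17, near the 25th percentile of the arrays, so these differences may be lower bounds.

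The most lowered genes in Cre without tamoxifen were the pyrimidine catabolism gene Dpys (-4.01, SE 0.127), the extracellular matrix gene Frem2 (-3.72, SE 0.085), Rian (-3.60, SE 0.074), Nrsn1 (-3.43, SE 0.074) and Styk1 (-3.34, SE 0.070). For Rian, Nrsn1 and Styk1 the Cre groups differed by -0.0044, 0.060 and 0.078 and were not called. Trophectoderm genes were called higher in the Cre cells before tamoxifen, with 19 of 28 higher and 4 lower (Tfap2c, Fgfr2, Cdh3 and Atp1b1), also adjusted over the list alone, and a median of 0.53 (adjusted p = 0.000522). That call was lost, with adjusted p = 0.0787 with an estimated correlation. Cdx2 was 1.82 higher (SE 0.136), Gata3 1.00, Hand1 0.86 and Eomes 0.74, while Tfap2a (0.15) and Tpbpa (0.016) were not called. The other lists were not called. Pluripotency genes had 16 of 26 higher and 7 lower (17 and 7 adjusted over the list alone; adjusted p = 0.189), with Pou5f1 0.46 higher, Nanog 0.36 higher and Sox2 at -0.51. The germline list had 14 of 27 higher and Sycp3, Stag3, Smc1b and Tdrd12 lower (15 and 4 adjusted over the list alone; adjusted p = 0.0555), and Dazl was 2.16 higher (SE 0.050). Without the first array of the cells without Cre, the germline list was called (camera adjusted p = 0.0179). With an estimated correlation it was far from a call (camera adjusted p = 0.326).

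Limma called 9221 genes (50.7%) between the controls, 4968 higher and 4253 lower in the cells with Cre. With arrays centred on their medians 4447 were higher and 4576 lower, so this balance too depends on the scaling. At least 2-fold were 971, 460 higher and 511 lower, against 2057 and 2439 in the comparisons with the Cre plus tamoxifen group.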

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

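The tests for the 3 patterns weighed here (the 2-cell genes, Meg3 with its neighbours and the fibroblast genes) were chosen after their results were seen, while the counts of other splits were planned. Transcripts of B1 repeats, a family of short interspersed elements read by a control probe set outside the gene comparisons, were 0.78 higher (log2, SE 0.064, adjusted p = 4.48e-06) in Cre plus tamoxifen than in Cre alone and 0.52 higher (adjusted p = 7.34e-05) than in tamoxifen alone. Of the 2 control probe sets for B2 repeats, 1 was at -0.43 (limma adjusted p = 0.000142) against Cre alone and -0.060 (not called) against tamoxifen alone. The other was at -0.070 and 0.0008 (neither called). Its values of 14.94 to 15.04 were the highest on each array, so a change may not show there. Of the 9160 probe sets with no gene symbol, 75 (0.819%) were at least 2-fold higher than in both controls. Of the 932 with several symbols, 51 (5.47%) were, beside 4.3% of the 34945 with 1 symbol. Single arrays were not tested for distance from their group, because the rule set for this takes groups of at least 4 arrays.

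Genes of the 2-cell stage were higher by a median of 3.04 in Cre cells without tamoxifen than in cells without Cre. Deletion of Setdb1 in part of the Cre cells before tamoxifen would lower Setdb1, by -0.33 if 34.6% of cells were deleted, the median share that these genes would need. Setdb1 was 0.35 higher instead, which argues against it unless the cells started from unlike Setdb1 levels. Trophectoderm genes would need a share of 6.7%. The shares rest on the 8 and 21 list genes called at least 2-fold higher in Cre plus tamoxifen than without Cre. They assume that cells deleted before tamoxifen respond as the induced cells do. That was not tested, so no conclusion is drawn from the unlike shares. Copy number of a whole chromosome would show as a block near 0.585, while the largest chromosome median was 0.095. Lowering by tamoxifen and a difference between the cells with and without Cre cannot be told apart and stay open, since the treated Cre cells, with a median 0.97 higher than in untreated ones, had also lost Setdb1 and were 4.78 higher than the treated cells without Cre.

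The noncoding RNA genes Meg3, Rian and Mirg, which lie together in an imprinted region, were at -3.10, -3.60 and -2.13 in Cre alone against tamoxifen alone. Tamoxifen alone would put treated Cre cells at the level of the treated cells without Cre, but the smallest of the 3 differences there was -2.24. The induced deletion would lower them further, but between the Cre groups the lowest of the 3 differences was -0.11. So neither alone explains both groups, though a rise with tamoxifen offset by a fall with the deletion was not excluded. A candidate explanation that also stays open and untested is a difference between the cells with and without Cre, such as in the imprint of this region.

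Some genes of the fibroblast list rose with Cre and tamoxifen, Tagln, Pdgfrb and Col5a2 among them. Acta2 did so only on a probe set of the s type (-0.0187 without such sets), but its other probe sets were dim (mean log2 values of 3.59 and 3.71). The call of the list against no Cre was lost with an estimated correlation (camera adjusted p = 0.0621). Admixed fibroblasts would bring their abundant collagen transcripts, but Col1a1, Col1a2, Col3a1, Dcn and Postn had a median difference of at most 0.18. In those cells Col1a1 was at 5.39, the 31.7th percentile of all genes, and Col3a1 at the 5.5th, while Tagln was at the 99.4th. The growth conditions in the labels name no feeder cells. A biological explanation, a change within the cells themselves, stays open as a hypothesis and was not tested.

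For each of the 3 comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The real splits gave 10198, 10781 and 9221 genes and the highest other split 0 in each (limma; 342, 302 and 602 at an unadjusted p under 0.05), so that 1 of 10 splits reached the real count. For genes called against both controls, 1 of 100 drawn regroupings, the real one, gave as many as 7242. The highest other gave 5415. That regrouping kept the 3 groups whole and exchanged their roles, which points to differences between all 3 groups. For the 3 against 6 contrast, 1 of 84 splits reached the 7239 genes of the real split fitted as 2 groups. The highest other split, cells without Cre against the rest, gave 4405. Splits that mixed groups gave 0 with limma, and at most 912 genes at an unadjusted p under 0.05. In such splits the differences between groups enter the residual spread and lower the count, so their 0 does not measure false calls. By rank alone, no other assignment that was tried reached the counts against both controls or against their mean. The arrays of a group may come from a single culture, however, so chance differences between cultures are not excluded.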

How the results depend on the processing

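The fit without the third array of both Cre groups was chosen after the data were seen; the other alternatives were planned. Of the 273 differences of named genes, 254 kept their direction and their side of the threshold under every alternative that gave them a value; 24 had none under the dim filter and 3 none without probe sets of the x and s types, and the 2-fold minimum was applied to counts of genes only. Of 5160 values 30 lost the call, 11 gained it and 3 reversed. Without probe sets of the x and s types, Acta2 went from 3.65 to -0.0187 (adjusted p = 0.853) in Cre plus against minus tamoxifen and from 2.38 to -0.0577 (adjusted p = 0.548) against no Cre, because a dim probe set then stood for it. With the mean of probe sets, which disagreed, Dnmt3a went from 0.084 to -0.44 (adjusted p = 2.56e-05) between the controls. Most losses were between the controls, as for Lefty2, Pdgfrb and Lama1; against no Cre, Nodal (0.101) and Nes (0.551) lost the call with the mean of probe sets. In Cre plus against minus tamoxifen, Frem2 (0.28) lost it without array 3 of Cre alone (0.0601), array 2 (0.0562) or 3 (0.0565) of Cre plus tamoxifen, or the third arrays of both Cre groups (0.147). In the order Cre plus against minus tamoxifen, Cre plus against no Cre, the controls against each other, both controls and their mean, testing every probe set called 18977, 21099, 17061, 12955 and 20890 because more features were tested. With median centring 5343, 5686, 4447, 4031 and 5621 of the called genes were higher and 4683, 5039, 4576, 3172 and 4977 lower, and with quantile normalization 4811, 5407, 4838, 3640 and 5158 higher and 5396, 5405, 4247, 3661 and 5555 lower. A 2-fold minimum left 2057, 2439, 971, 1357 and 1961. Leaving out each array in turn gave 9617 to 10190, 10084 to 10836, 8324 to 9200, 6834 to 7084 and 9972 to 10703, and the other settings 8729 to 10329, 8995 to 10858, 8024 to 9480, 6486 to 7406 and 9011 to 10814. Fitting only the groups compared applies to no contrast with a mean of groups. Without the third array of both Cre groups 9523, 10331, 8834, 6850 and 10065 were called. The replicate numbers did not pair the arrays: the 9 same-numbered pairs correlated at -0.0884 to 0.0568 after removal of group means. A replicate block gave 10058, 10625, 9062, 7099 and 10563 genes, and its only changed list was primitive endoderm in the first comparison (adjusted p = 0.0419). Between the controls, the germline list was called with the dim filter (0.0406), every probe set (0.00118), the mean of probe sets (0.0433) and fry (1.92e-05). It ranged from 0.0179 to 0.0995 with single arrays left out and was at 0.326 with an estimated correlation. The trophectoderm list was lost with an estimated correlation (0.0787), and the pluripotency list was called by fry (3.04e-05). Fry tests whether a list moves and not whether it moves more than other genes. The cause of the germline, trophectoderm and pluripotency changes was not tested. Over all 45 list results, 842 of 900 values kept their call, 17 lost it, 41 gained it and 0 reversed. Primitive endoderm in Cre plus against minus tamoxifen was called under 12 of 20 alternatives, namely quantile normalization (0.0369), every probe set (0.00115), mean of probe sets (0.0176), no x and s types (0.0321), only the groups compared (0.0399), the block above, fry (4e-08) and the fits without array 1 (0.0487), 2 (0.0412) or 3 (0.0479) of the cells without Cre, array 3 of Cre alone (0.0498) or array 2 of Cre plus tamoxifen (0.0482). Stress response in Cre plus against no Cre was lost under 9 of 20, namely median centring (0.054), the dim filter (0.132), no x and s types (0.0541), only the groups compared (0.0514), an estimated correlation (0.0894) and the fits without array 2 of the cells without Cre (0.0533), array 1 (0.0512) or 2 (0.0525) of Cre alone or array 2 of Cre plus tamoxifen (0.0523). In that comparison fibroblast genes were lost with the dim filter (0.35), no x and s types (0.069) and an estimated correlation (0.0621), and primitive endoderm with the dim filter (0.274) and an estimated correlation (0.061). The dim filter also lost the fibroblast (0.0808) and imprinted (0.0503) lists in the first comparison. Imprinted genes between the controls were called without array 3 of Cre alone (0.0456), without the third arrays of both Cre groups (0.0441), with every probe set (0.00118) and by fry (2.62e-07). Every probe set also called neuroectoderm (0.00118) and p53 targets (0.0047) between the controls and stress response in the first comparison (0.00115), and fry gained 20 calls in all. Dim genes limit the precision, since a difference between signals near background understates the change.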

Other observations

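The gene families and single genes in the first paragraph were chosen after their values were seen, and the lists and the tests of neighbouring genes below were written after the main results and before their own values were seen. All 4 measured Rhox genes, an X-linked homeobox cluster used in reproductive tissues, rose in Cre plus tamoxifen against both controls, under quantile normalization and median centring too. Rhox5 rose by 1.29 and 0.63 and Rhox13 by 1.77 and 2.29 (against Cre alone and against tamoxifen alone), beside the larger rises of Rhox6 and Rhox9. Of 11 annexin genes, whose proteins bind membranes in a calcium-dependent way, 9 rose against each control. Anxa1 rose by 3.56 and 4.36, Anxa5 by 3.75 and 3.38, and Anxa10 and Anxa13 were not called. Of 18 genes of the Serpinb protease inhibitors, 10 rose and Serpinb1a and Serpinb6c fell against Cre alone, and 9 rose and Serpinb6c fell against tamoxifen alone. Serpinb9b (3.06 and 4.60), Serpinb9c (3.18 and 3.09) and Serpinb9g (2.85 and 3.02) rose, though these near-identical genes may share probes. In Cre alone and tamoxifen alone, Serpinb9c (3.60 and 3.69) and Serpinb9g (3.64 and 3.48) lay below the arrays' 25th percentile (4.13 to 4.21). The differences of these 2 genes are thus lower bounds. The tests of neighbouring genes below left out pairs of Serpinb genes and still counted 76. The desmosome genes Dsp (3.65 and 3.51) and Dsc2 (3.55 and 3.06) and the macrophage elastase gene Mmp12 (4.13 and 4.68) also rose. Genes that fell included the 5-methylcytosine dioxygenase gene Tet1 (-2.39 and -3.02), Mycn (-2.92 and -2.73), the Polycomb gene Phc1 (-2.30 and -2.78), the receptor gene Kit (-2.31 and -2.40) and Eras (-2.13 and -2.53).

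A first hypothesis was that targets of FGF/ERK signalling fell along with Fgf4. The list left out Spry4 and Egr1, whose falls had been seen. Of 10 measured genes, 7 fell and 2 rose against Cre alone, and 9 fell and 1 rose against tamoxifen alone, with the same counts adjusted over the list alone. Etv4 fell by 2.14 and 1.07, Etv5 by 1.15 and 2.03, Spry2 by 1.54 and 1.05 and Dusp6 by 1.18 and 0.86. Phlda1 rose by 1.13 and 2.57, and Dusp4 rose by 0.51 against Cre alone only, with a fall of 0.40 against tamoxifen alone. The list was called lower in both comparisons (camera adjusted p = 0.0104 and 0.000302). Against Cre alone the call was lost (adjusted p = 0.124 with an estimated correlation), and against tamoxifen alone it held (adjusted p = 0.0451 with an estimated correlation). Lower FGF/ERK activity may accompany the deletion, but transcripts alone do not measure it.

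A second hypothesis was that targets of the YAP and TEAD factors, which act in trophectoderm and in spread cells, rose along with Ankrd1, which was left out of the list. Of 20 genes, 14 rose and Fjx1 fell against Cre alone (17 and 2 adjusted over the list alone), and 15 rose and Fjx1 and Dock5 fell against tamoxifen alone (15 and 2). Ccn1 rose by 2.45 and 2.14, F3 by 3.02 and 1.97, Crim1 by 3.10 and 2.02 and Myof by 2.89 and 3.04. The list was called higher in both comparisons (adjusted p = 1.5e-06 and 5.91e-05; adjusted p = 0.00515 and 0.0116 with an estimated correlation). Between the controls neither this list nor the FGF/ERK list was called (adjusted p = 0.435 for each). Greater YAP/TEAD activity may accompany the deletion, but a change of cell shape or lineage could give the same transcripts and was not tested.

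The last hypothesis was that genes that rose together lie next to one another. Of 18030 genes placed on the GRCm38.p6 annotation, 972 rose at least 2-fold against both controls, and 92 pairs of neighbours among measured genes both rose, against a mean of 52.1 in 1000 permutations within chromosomes. With pairs of the same name stem left out, 76 pairs remained, against a mean of 48.3 and a highest value of 69. The stem was the starting letters of a name. Names with too few of them, such as Gm genes and clone names, were not matched, so related neighbours may remain among the 76. The permutation p was 0.001, the smallest that 1000 permutations can give. Neighbouring genes may thus share a release from repression, although tissue-specific genes also cluster along chromosomes, which was not tested.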
